A study of Mus musculus with 18 samples.

How the data were processed

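Expression was measured on Affymetrix mouse genome arrays with total RNA from CD11b+ dendritic cells, in 6 groups of 3 arrays. Per the labels' protocols, C57BL/6 bone marrow was cultured with FLT3L at 100 ng/ml for 8 days, CD11b+ cells were purified by magnetic separation and stimulated for 4 h with curdlan at 1 or 100 μg/ml, with or without GM-CSF at 5 ng/ml. The values are the probe set intensity that the authors deposited, summarised with RMA under R 2.13.2 per the submitters' processing notes. That they are on the linear scale was inferred from the values, which reach 17270.0 to 18433 per array, while array medians run from 49.8 to 51.2. The background and normalization settings and the package version within RMA stay unknown. The arrays' number, 3 per group, limits the precision, and RMA intensities near the low end understate fold changes. Ratios of 3' to 5' control probe sets were 1.14 to 1.23 for Actb and 0.978 to 1.04 for Gapdh.

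Of 45101 probe sets, 34945 were annotated to 1 gene, 932 to several, 9160 to none in the gene table used and 64 were controls. Symbols were brought up to date through the Entrez number for 34741 of them, from a RefSeq gene table used for names alone. The 18193 genes with a probe set of their own included 9010 with more than 1, and each gene took the probe set with the highest mean log2 value. Genes entered the test when the log2 value was at least 5 (an intensity of 32) in at least 3 of the 18 arrays, which kept 13092 and left out 5101. Values were read in R 4.3.3 with the package data.table, version 1.17.8. The log2 values of all 18 arrays were fitted with lmFit and eBayes of limma 3.58.1 with 1 mean per group, no replicate block and no covariates, and p-values were adjusted by Benjamini-Hochberg over all tested genes within each comparison, with 0.05 as the threshold for a gene that passes.

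The comparisons were GM-CSF, curdlan 1 and curdlan 100 against unstimulated cells; curdlan 100 against curdlan 1; GM-CSF added to each curdlan dose; each curdlan dose added to GM-CSF; and the doses against each other in the presence of GM-CSF. For each dose the interaction is the GM-CSF effect with curdlan minus that without it, which on the log2 scale measures departure from the product of the single effects. The difference of the GM-CSF effects between the doses was tested in the same way. As an alternative the combination was compared with the sum of the single increments over the unstimulated level on the linear scale, with errors by the delta method and limma's moderated variances. Gene lists were written from general knowledge of Dectin-1 and GM-CSF signalling, of metabolism and of the markers of other cells that such cultures could hold. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. Unless said otherwise, a list's p is the camera value at the preset, and where no second value stands beside one under 0.05 the call held with the estimated correlation. The number of passing members is given as adjusted over all genes and as adjusted over the list alone.

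Genes named in the text followed a rule. For each comparison it took the 8 largest increases and 8 largest decreases among passing genes whose groups did not overlap, clones and predicted genes aside; that condition was not set for the interactions. It also took up to 4 passing members of each list with the largest changes, or the largest value where none passed. Fixed in any comparison were Il2, Il10, Il6, Il12b, Il23a, Tnf, Il1b, Csf2, Ptgs2, Cish, Ccl17, Ccl22, Clec7a, Csf2ra and Csf2rb. Groups, comparisons, gene lists, this rule and all but 1 of the alternatives were fixed before the data were examined. Alternatives were the mean over a gene's probe sets, no filter or a log2 value of at least 7, quantile normalization, centring of each array on its median, trended and robust eBayes, array quality weights, the replicate number as a block, a fit of the compared groups alone, a minimum change of 2-fold, the sum of single increments for the interactions, and leaving out each array in turn. A further alternative, with intensities under 32 set to 32, was chosen after the values were seen. The procedure was tested on simulated data of 13092 genes with the arrays' own spread. For GM-CSF against unstimulated cells 94% of 1.41-fold and 100% of 2-fold and 4-fold changes were recovered, for the interaction at curdlan 100 these shares were 82%, 99% and 100%, and for the sum 78%, 96% and 100%; between 0.0543% and 0.0855% of unchanged genes were called. Camera called 20 of 20 simulated lists shifted by 0.3 and none of 80 that were not shifted. The simulated genes were drawn independently, so this does not test how correlation between genes affects the list p-values. In each simulation 12892 of 13092 genes were unchanged, while 5259 genes passed for GM-CSF alone and 3701 for curdlan 100 alone. The share of unchanged genes called may therefore not hold for those comparisons. Their passing genes had median absolute log2 changes of 0.301 and 0.277, below the smallest simulated log2 change of 0.5. How often changes under 0.5 are recovered was not tested. The 4659 expressed probe sets that were annotated to several genes or to none were left out of the comparisons.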

Results

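Gene expression was measured in CD11b+ dendritic cells that were grown from C57BL/6 mouse bone marrow with FLT3 ligand (FLT3L) at 100 ng/ml for 8 days. Cells were stimulated for 4 h with GM-CSF at 5 ng/ml, a cytokine that signals through JAK2 and STAT5, with curdlan at 1 or 100 μg/ml, a β-glucan particle that engages the receptor Dectin-1, or with both. The 6 groups of 3 arrays each were unstimulated cells, GM-CSF alone, each curdlan dose alone (called curdlan 1 and curdlan 100 here), and each curdlan dose with GM-CSF; the labels do not state how long the unstimulated cells were kept. After the filter on low signals 13092 genes were tested. The series title names synergism between the agents, so each agent was tested alone, on top of the other, and for departure from the product of the single effects. The first principal component held 54.5% of the variance and ran from the unstimulated arrays (scores of -26.7 to -25.8) to those of curdlan 100 with GM-CSF (25.4 to 28.6). The second held 21.9% and had GM-CSF alone (16.6 to 18.8) and curdlan 100 alone (-17.4 to -16.1) at opposite ends. Changes are log2 values ± SE from the fit of all 18 arrays, and levels are mean intensities ± SD, with n = 3 arrays per group. Where the mean of a compared group lay under the filter's intensity of 32, a change is given as at least the value found with intensities under 32 set to 32. For interactions and sums of single increments such a value is not a lower bound. Adjusted p-values beside values with that setting, interactions included, come from the fit of the intensities as measured. The number of arrays limits the precision, and nothing in the labels says that replicates were separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

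GM-CSF alone raised most targets of its own signalling and a set of chemokine genes, and members of the interferon response and cell cycle lists fell. The list calls for chemokines, interferon responses and cell cycle were lost with an estimated correlation (adjusted p = 0.0982, 0.637 and 0.345). Ccl12, Ccl7 and Ccl2, which encode chemokines that attract monocytes, rose by 4.76 ± 0.16, 3.66 ± 0.08 and 3.30 ± 0.11. Ccl17, whose product attracts T cells through CCR4, rose by 4.11 ± 0.11, or 17.3-fold. Cish, a feedback inhibitor of STAT5 signalling, rose by 3.07 ± 0.08, Plet1, a surface protein gene, by at least 4.07 and Hbegf, a ligand of the EGF receptor, by 2.82 ± 0.08. The largest decreases among named genes were those of Hpgd, which inactivates prostaglandins (-1.91 ± 0.07), and Il12b, the p40 subunit of IL-12 and IL-23 (-1.91 ± 0.08). Gpr34 (-1.81 ± 0.11) and the prostaglandin receptor gene Ptger3 (-1.70 ± 0.10) followed. The largest adjusted p among these genes was 2.71e-09. In limma 5259 of 13092 genes passed, 1928 higher and 3331 lower, and 170 of them moved at least 2-fold, 112 higher and 58 lower.

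Of the response lists, the one of GM-CSF's known targets had the largest median change (1.03). Of 22 measured STAT5 and GM-CSF target genes 18 rose, 2 fell and 2 did not pass (19 and 3 adjusted over the list alone; adjusted p = 4.91e-14). With an estimated correlation camera gave an adjusted p of 0.0091. Socs3 rose by 2.60 ± 0.09 and Ccnd2, which encodes cyclin D2, by 2.08 ± 0.08. Among 23 chemokine genes 12 rose, none fell and 11 did not pass (12 and 1 adjusted over the list alone; adjusted p = 8.64e-09, but adjusted p = 0.0982 with an estimated correlation). Of 18 dendritic cell maturation genes 11 rose, 2 fell and 5 did not pass (12 and 2 adjusted over the list alone; adjusted p = 6.33e-05, but adjusted p = 0.0982 with an estimated correlation). The genes of PD-L2, Pdcd1lg2 (1.94 ± 0.10), and of the costimulator Cd80 (1.39 ± 0.06) led that list. In the list of 23 immediate early and NFAT-linked genes 13 rose, 4 fell and 6 did not pass (13 and 4 adjusted over the list alone; adjusted p = 4.15e-05, but adjusted p = 0.152 with an estimated correlation). Nr4a3 moved by 1.59 ± 0.06 and Egr1 by 1.42 ± 0.06. Cytokine genes went both ways: 9 rose, 4 fell and 10 did not pass (9 and 4 adjusted over the list alone; adjusted p = 0.0207, but adjusted p = 0.152 with an estimated correlation). Il1b stood at 1.77 ± 0.08, Osm at 1.30 ± 0.10 and Tnf at 0.80 ± 0.06. Among 17 NF-kB feedback genes 9 rose, 1 fell and 7 did not pass (9 and 1 adjusted over the list alone; adjusted p = 0.00057, but adjusted p = 0.265 with an estimated correlation), and Nfkbie moved most (0.93 ± 0.07). Cholesterol biosynthesis genes moved by little, yet 12 rose, none fell and 4 did not pass (13 and 0 adjusted over the list alone; adjusted p = 9.19e-06, but adjusted p = 0.152 with an estimated correlation). Hsd17b7 (0.59 ± 0.07) and Cyp51 (0.43 ± 0.05) are examples.

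Some gene groups were lower with GM-CSF. Of 23 type I interferon response genes none rose, 12 fell and 11 did not pass (0 and 12 adjusted over the list alone; adjusted p = 0.02, but adjusted p = 0.637 with an estimated correlation). The antiviral genes Rsad2, Ifit1 and Mx1 fell, with values of -1.44 ± 0.12, -0.95 ± 0.12 and -0.86 ± 0.10. Where the filter asked for a log2 value of 7, camera gave this list 0.0534, and over left-out arrays at most 0.0341. The 24 cell cycle genes gave small decreases: none rose, 18 fell and 6 did not pass (0 and 20 adjusted over the list alone; adjusted p = 0.000224, but adjusted p = 0.345 with an estimated correlation). Among them were Rrm2, a subunit of ribonucleotide reductase (-0.35 ± 0.06), and E2f1 (-0.34 ± 0.06). In the prostanoid and leukotriene pathway 2 rose, 7 fell and 7 did not pass (3 and 7 adjusted over the list alone; adjusted p = 0.191). Hpgd and the receptor gene Ptger2 (-1.24 ± 0.06) were among those that fell. For 14 extracellular proteolysis genes 6 rose, 1 fell and 7 did not pass (6 and 1 adjusted over the list alone; adjusted p = 0.00457, but adjusted p = 0.152 with an estimated correlation). They include the collagenase gene Mmp13 (1.69 ± 0.12) and the urokinase gene Plau (1.22 ± 0.09). Of 16 unfolded protein and amino acid stress genes 7 rose, 2 fell and 7 did not pass (8 and 2 adjusted over the list alone; adjusted p = 0.00919, but adjusted p = 0.152 with an estimated correlation), and Pdia4 moved by 0.83 ± 0.05. MHC class II presentation genes moved by less, and 6 rose, 1 fell and 6 did not pass (7 and 1 adjusted over the list alone; adjusted p = 0.0214, but adjusted p = 0.331 with an estimated correlation). Ciita, the class II transactivator, stood at 0.47 ± 0.05. Members of 4 further lists went both ways and camera gave no call. For curdlan receptor and Syk-CARD9 signalling 7 rose, 7 fell and 6 did not pass (7 and 7 adjusted over the list alone; adjusted p = 0.191). Clec4n, the gene of Dectin-2, stood at 1.51 ± 0.08. Inflammasome genes counted 4 higher, 5 lower and 2 not passing (4 and 6 adjusted over the list alone; adjusted p = 0.952). Glycolysis and glucose uptake genes counted 2 higher, 6 lower and 12 not passing (3 and 6 adjusted over the list alone; adjusted p = 0.931), and oxidative burst and antioxidant genes 4 higher, 6 lower and 5 not passing (4 and 7 adjusted over the list alone; adjusted p = 0.952). Medians and means differed in sign for the curdlan receptor list (-0.03 and 0.18) and the inflammasome list (-0.16 and 0.05), and in both the test's direction was that of the mean. They also differed for the oxidative burst list (-0.06 and 0.00405), where the test's direction was that of the median.

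Curdlan at the low dose raised a compact inflammatory set. Cxcl2, whose product attracts neutrophils, rose by 3.80 ± 0.10 (14.0-fold), Acod1, the enzyme that makes itaconate, by 2.49 ± 0.10, Il1b by 2.02 ± 0.08 and Tnf by 1.78 ± 0.06. Clec4e, which encodes the receptor Mincle, rose by 1.92 ± 0.08 and Olr1, a receptor for oxidised LDL, by at least 0.77. The anticoagulant receptor gene Thbd fell by 0.60 (SE 0.09), and the largest adjusted p of these was 0.000914. All 17 measured NF-kB feedback genes rose, Nfkbie by 1.38 ± 0.07 and Nfkbia by 1.13 ± 0.05. As a list they gave adjusted p = 1.87e-56, and 0.000113 with an estimated correlation (17 adjusted over the list alone). Of 23 immediate early and NFAT-linked genes 17 rose, 2 fell and 4 did not pass (18 and 3 adjusted over the list alone; adjusted p = 1.01e-27). Ptgs2, the inducible cyclooxygenase, moved by 1.56 ± 0.10 and Egr3 by 1.44 ± 0.08. For 23 chemokine genes, 8 rose, none fell and 15 did not pass (8 and 0 adjusted over the list alone; adjusted p = 4e-14). For 23 cytokine genes, 5 rose, none fell and 18 did not pass (6 and 0 adjusted over the list alone; adjusted p = 1.1e-07). No interferon response gene passed at this dose, although the list as a whole lay higher (median 0.10; adjusted p = 0.0118, but adjusted p = 0.492 with an estimated correlation). Camera gave that list 0.0544 without curdlan 1 replicate 1 and 0.0656, the highest over left-out arrays, without unstimulated replicate 3. In all, 403 genes passed, 229 higher and 174 lower, and each of the 17 that moved at least 2-fold was higher. That count was 215 without unstimulated replicate 1, 166 with the fit of these groups alone and 666, of which 332 higher and 334 lower, with trended, robust variances.

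Curdlan at the high dose also raised 18 of 23 interferon response genes. Cxcl2 rose by 5.48 ± 0.10 (44.6-fold), Acod1 by 4.86 ± 0.10, Olr1 by at least 3.10, Cxcl3, another neutrophil attractant, by at least 2.47, Il1b by 3.46 ± 0.08 and Tnf by 3.25 ± 0.06. Hpgd fell by 1.46 (SE 0.07) and the prostaglandin receptor genes Ptger3 and Ptger2 changed by -1.28 ± 0.10 and -1.27 ± 0.06. The largest adjusted p of these was 5.92e-08. All 17 NF-kB feedback genes rose again, with a median of 1.34 (17 adjusted over the list alone; adjusted p = 1.87e-35). Of 23 interferon response genes 18 rose, none fell and 5 did not pass (18 and 0 adjusted over the list alone; adjusted p = 6.48e-15), and Rsad2 stood at 1.94 ± 0.12. An estimated correlation gave an adjusted p of 0.0415. Among chemokine genes 20 rose, none fell and 3 did not pass (20 and 0 adjusted over the list alone; adjusted p = 6.22e-20). Among cytokine genes 13 rose, 1 fell and 9 did not pass (14 and 1 adjusted over the list alone; adjusted p = 2.52e-11), with Il1a at 2.35 ± 0.08 and the interleukin-1 antagonist Il1rn at 2.07 ± 0.10. For dendritic cell maturation, 15 rose, none fell and 3 did not pass (16 and 0 adjusted over the list alone; adjusted p = 6.48e-15). The costimulatory receptor gene Cd40 led (2.27 ± 0.07). Oxidative burst and antioxidant genes were higher too: 10 rose, none fell and 5 did not pass (10 and 0 adjusted over the list alone; adjusted p = 1.39e-08). Sulfiredoxin, Srxn1, stood at 1.10 ± 0.06 and Sod2 at 1.02 ± 0.04. STAT5 and GM-CSF target genes moved without added GM-CSF: 18 rose, none fell and 4 did not pass (18 and 1 adjusted over the list alone; adjusted p = 6.45e-14). Ccl17 rose by 2.59 ± 0.11, and Cish stood at 0.66 ± 0.08. In limma 3701 genes passed, 1363 higher and 2338 lower, and of 144 that moved at least 2-fold 131 were higher.

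Members of further lists also moved with curdlan 100. For cell cycle genes, none rose, 13 fell and 11 did not pass (0 and 17 adjusted over the list alone; adjusted p = 0.000349, but adjusted p = 0.297 with an estimated correlation), with Cdc6, a replication licensing factor, at -0.46 ± 0.07. For cholesterol biosynthesis, 10 rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone; adjusted p = 1.86e-05, but adjusted p = 0.125 with an estimated correlation), with Idi1 at 0.40 ± 0.06. Of the curdlan receptor and Syk-CARD9 genes 10 rose, 2 fell and 8 did not pass (12 and 3 adjusted over the list alone; adjusted p = 2.07e-06, but adjusted p = 0.0551 with an estimated correlation). Clec4e stood at 3.80 ± 0.08 and Tlr2 at 2.32 ± 0.06. Of 20 glycolysis and glucose uptake genes 6 rose, 2 fell and 12 did not pass (6 and 2 adjusted over the list alone; adjusted p = 0.0415, but adjusted p = 0.425 with an estimated correlation). The transporter genes Slc2a6 and Slc2a1 stood at 1.73 ± 0.07 and 0.81 ± 0.07. That list's median of 0.01 turned to -0.0042 when arrays were centred on their medians. Its camera p passed 0.05 in several alternatives, up to 0.159 without curdlan 100 replicate 3, the highest over left-out arrays. Directly against curdlan 1, curdlan 100 raised 1058 genes and lowered 1335 of 2393 that passed, 54 of them at least 2-fold and 52 of those higher. That balance turned with the fit of these groups alone (645 higher and 612 lower of 1257) and without curdlan 100 replicate 3 (988 and 970.0). Cxcl3 differed by 2.38 ± 0.15, Acod1 by 2.37 ± 0.10, Olr1 by 2.32 ± 0.07 and Ccl17 by 1.94 ± 0.11. Ifit1 differed by 1.86 ± 0.12 and Hpgd by -1.22 ± 0.07, with a largest adjusted p of 2.53e-08. Between the doses the 23 interferon response genes counted 18 higher, none lower and 5 not passing (21 and 0 adjusted over the list alone; adjusted p = 6.95e-17) at the high dose. The 23 immediate early and NFAT-linked genes counted 18 higher, 1 lower and 4 not passing (18 and 1 adjusted over the list alone; adjusted p = 8.12e-22).

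**Figure D1:**
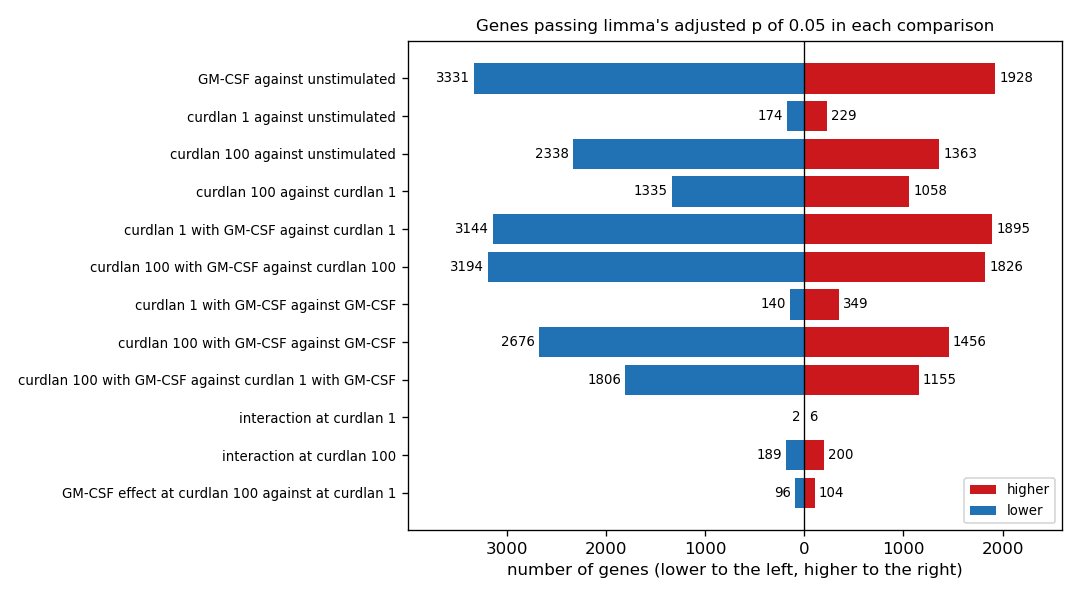
Bars give, for each comparison, the number of genes with an adjusted p under 0.05 in limma, of 13092 tested, with lower genes to the left and higher genes to the right of 0. Adding GM-CSF moved 5020 to 5259 genes at each curdlan level, curdlan 1 moved 403 or 489, and the interactions held 8 and 389.

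GM-CSF added to curdlan raised most STAT5 target genes and 14 of 23 chemokine genes at each dose, while its effect on Il12b and on members of the interferon response list went opposite ways at the low and the high dose. Ccl12 rose by 4.76 ± 0.16 over curdlan 1 and by 3.38 ± 0.16 over curdlan 100, Plet1 by at least 4.11 and 4.57, and Cish by 3.11 ± 0.08 and 2.76 ± 0.08. Il12b changed by -1.10 ± 0.08 over curdlan 1 and by 0.52 ± 0.08 over curdlan 100 (adjusted p = 2.6e-08 and 0.000114). That difference between the doses was 1.62 ± 0.11 (adjusted p = 1.61e-06), and for the interferon response list its median was 0.76, with adjusted p = 4.89e-35. That list's calls over each dose by itself were lost with an estimated correlation (adjusted p = 0.641 and 0.0897). Il2, the T cell growth factor, rose by at least 1.91 over curdlan 100 (adjusted p = 4.71e-10). F3, which encodes tissue factor, rose by 3.09 ± 0.12 and Edn1, which encodes endothelin-1, by 2.44 ± 0.16. Ptger3 fell at both doses, by 1.85 (SE 0.10) and 1.72 (SE 0.10). Gpr34 fell by at least 1.70 and 1.14, and Slc40a1, the iron exporter ferroportin, changed by -1.70 ± 0.07 and -1.38 ± 0.07. At the low dose 5039 genes passed (1895 higher, 3144 lower, 160 at least 2-fold) and at the high dose 5020 (1826 higher, 3194 lower, 132 at least 2-fold).

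Gene groups moved with these genes. Of 22 STAT5 and GM-CSF targets, GM-CSF left 18 higher, 2 lower and 2 not passing (18 and 2 adjusted over the list alone; adjusted p = 1.77e-14) over curdlan 1. Over curdlan 100 these were 17 higher, 2 lower and 3 not passing (17 and 2 adjusted over the list alone; adjusted p = 9.68e-14). Chemokine genes counted 14 higher, none lower and 9 not passing (14 and 0 adjusted over the list alone; adjusted p = 7.44e-12) at the low dose and 14 higher, none lower and 9 not passing (16 and 0 adjusted over the list alone; adjusted p = 3.61e-14) at the high dose. Of 23 interferon response genes 2 rose, 11 fell and 10 did not pass (3 and 12 adjusted over the list alone; adjusted p = 0.0277, but adjusted p = 0.641 with an estimated correlation) over curdlan 1. Rsad2 stood at -1.22 ± 0.12 and Mx1 at -0.90 ± 0.10. That call ended with array weights (0.0505), with a log2 value of at least 7 (0.069) and without the second array of curdlan 1 with GM-CSF (0.0567, the highest over left-out arrays). Over curdlan 100 the same list gave the other direction: 21 rose, none fell and 2 did not pass (22 and 0 adjusted over the list alone; adjusted p = 1.15e-11, but adjusted p = 0.0897 with an estimated correlation). Mx1 stood at 1.23 ± 0.10 and Usp18 at 1.13 ± 0.10. Cytokine genes counted 12 higher, 5 lower and 6 not passing (13 and 5 adjusted over the list alone; adjusted p = 0.000104) at the low dose. At the high dose they counted 14 higher, 1 lower and 8 not passing (14 and 1 adjusted over the list alone; adjusted p = 2.12e-11), and Osm rose by 2.42 ± 0.10 and Lta by 2.21 ± 0.16. For extracellular proteolysis genes at the high dose 9 rose, none fell and 5 did not pass (9 and 1 adjusted over the list alone; adjusted p = 6.5e-05, but adjusted p = 0.0508 with an estimated correlation). Mmp13 (1.75 ± 0.12) and the plasminogen activator inhibitor gene Serpinb2 (1.61 ± 0.12) were among them. Cell cycle genes counted none higher, 19 lower and 5 not passing (0 and 20 adjusted over the list alone; adjusted p = 0.000115, but adjusted p = 0.358 with an estimated correlation) at the low dose. At the high dose they counted none higher, 20 lower and 4 not passing (0 and 22 adjusted over the list alone; adjusted p = 5.52e-07, but adjusted p = 0.187 with an estimated correlation).

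Curdlan added to GM-CSF raised Cxcl2 and Cxcl3 at both doses, and at the high dose most interferon response genes. Cxcl3 rose by at least 4.56 with curdlan 100 over GM-CSF alone, Cxcl2 by 5.63 ± 0.10, Acod1 by 4.82 ± 0.10 and Ptgs2 by 4.64 ± 0.10. Ifit1 rose by 4.17 ± 0.12 and Rsad2 by 4.12 ± 0.12, and the cannabinoid receptor gene Cnr2 changed by -1.33 ± 0.08. The largest adjusted p was 2.24e-09. Curdlan 1 raised Cxcl2 by 4.16 ± 0.10, Cxcl3 by at least 1.83, Ptgs2 by 2.74 ± 0.10 and Il1a by 2.26 ± 0.08 over GM-CSF alone, with a largest adjusted p of 6.98e-10. The 23 cytokine genes counted 12 higher, none lower and 11 not passing (14 and 0 adjusted over the list alone; adjusted p = 1.56e-19) with curdlan 1. With curdlan 100 they counted 16 higher, 1 lower and 6 not passing (16 and 1 adjusted over the list alone; adjusted p = 1.63e-19), where Il12b rose by 3.23 ± 0.08 and Il1b by 3.91 ± 0.08. All 17 NF-kB feedback genes rose at each dose (adjusted p = 1.54e-67 and adjusted p = 1.56e-31), also when adjusted over the list alone. The 23 interferon response genes counted 2 higher, none lower and 21 not passing (4 and 0 adjusted over the list alone; adjusted p = 0.00268, but adjusted p = 0.532 with an estimated correlation) with curdlan 1. With curdlan 100 they counted 22 higher, none lower and 1 not passing (23 and 0 adjusted over the list alone; adjusted p = 3.04e-28). Curdlan 1 passed 489 genes (349 higher, 140 lower; 850 with array weights), the 29 with at least a 2-fold change all higher. Curdlan 100 passed 4132 (1456 higher, 2676 lower), 172 at least 2-fold and 159 of those higher. Between the doses in the presence of GM-CSF 2961 genes passed, 1155 higher and 1806 lower, which quantile normalization turned to 1374 higher and 1310 lower. All 67 that moved at least 2-fold were higher with curdlan 100. All 23 interferon response genes rose between these doses (23 adjusted over the list alone; adjusted p = 4.16e-34), Ifit1 by 3.77 ± 0.12 and Ifit2 by 3.15 ± 0.14, and Il2 rose by at least 1.91.

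The combination of curdlan 100 and GM-CSF exceeded the product of the single effects for 11 of 23 cytokine and 15 of 23 interferon response genes, while of 23 chemokine genes 6 fell short of it and 3 exceeded it. Il12b lay above the product by 2.43 ± 0.11 (adjusted p = 7.36e-09). GM-CSF alone took its level from 322 ± 13.9 to 85.5 ± 3.45, curdlan 100 alone to 563 ± 17.2 and the combination to 807 ± 80.3. Rsad2 (2.18 ± 0.18), Mx1 (2.08 ± 0.14), Ifit1 (2.04 ± 0.17), Edn1 (1.92 ± 0.22) and Inhba, a subunit of activin A (1.86 ± 0.13), also lay above the product. For a gene that GM-CSF lowers and curdlan raises, the product is smaller than the sum of the single increments by arithmetic. Il12b and Ifit1 are such genes, so their distance above the product is larger than that above the sum. Ifit1 had levels of 80.8 unstimulated, 42.1 with GM-CSF, 354 with curdlan 100 and 755 in the combination. The lists were tested against the product only. Ccl12 (-1.38 ± 0.23), Ccl4 (-1.09 ± 0.09) and Ccl17 (-0.99 ± 0.16) lay below the product. Against the sum of the single increments, however, all 3 turned positive, at 0.05, which did not pass, 0.33 and 1.23. For Ccl4 the level expected from the product exceeded the highest intensities of the arrays, 17270 to 18433. The arrays may therefore not have been able to show that level. The largest adjusted p of the values against the product was 0.00292. Il2 had a level of 121 ± 20.4 in the combination, while its means unstimulated (13.6), with GM-CSF (15.2) and with curdlan 100 (17.8) all lay under 32. The product for Il2 is therefore not measured, and its interaction, which passed (adjusted p = 1.6e-06), was 1.91 with intensities under 32 set to 32. Il2 is nevertheless counted among the 11 cytokine genes above the product. In limma 389 genes passed this interaction, 200 above and 189 below, and 28 of them by at least 2-fold, 24 above and 4 below. More genes lay below than above with array weights (269 and 254), with a log2 value of at least 7 (248 and 245), and without curdlan 100 replicate 3 (203 and 189), GM-CSF replicate 2 (178 and 173) or unstimulated replicate 2 (184 and 179).

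Against the product of the single effects, of 23 cytokine genes 11 lay above it, none lay below it and 12 did not pass (12 and 0 adjusted over the list alone; adjusted p = 2.02e-17). Il1a stood at 1.62 ± 0.11 and Csf2, which encodes GM-CSF itself, at 1.52 ± 0.17. Il6, with 2 of its 4 groups under 32, stood at 0.97 as measured and at 1.90 with intensities under 32 set to 32. That setting took its change with GM-CSF alone from 0.93 to 0, so the larger value is not a lower bound. An estimated correlation gave the list an adjusted p of 0.000182. Tnf gave an interaction of 0.02 ± 0.09 that did not pass (adjusted p = 0.955). Il1b gave one of 0.45 ± 0.12, whose adjusted p of 0.0496 rose above 0.05 in 15 of 23 alternatives, a minimum change aside, up to 0.124 without GM-CSF replicate 3. Of 23 interferon response genes 15 lay above it, none lay below it and 8 did not pass (17 and 0 adjusted over the list alone; adjusted p = 4.95e-33). Their median was 0.72, with an adjusted p of 0.00974 on an estimated correlation. Chemokine genes split: 3 lay above it, 6 lay below it and 14 did not pass (5 and 6 adjusted over the list alone; adjusted p = 0.46). Their median was 0.06 and their mean -0.03, with Cxcl3 at 1.68 ± 0.21, or 2.08 with intensities under 32 set to 32. STAT5 and GM-CSF targets leaned below the product: 1 lay above it, 5 lay below it and 16 did not pass (2 and 9 adjusted over the list alone; adjusted p = 0.000123, but adjusted p = 0.187 with an estimated correlation). Socs2 stood at -0.60 ± 0.08 and Myc at -0.59 ± 0.10, but Osm at 1.11 ± 0.14. For immediate early and NFAT-linked genes, 4 lay above it, 4 lay below it and 15 did not pass (6 and 5 adjusted over the list alone; adjusted p = 0.614). Ptgs2, whose means unstimulated and with GM-CSF lay close to the filter's intensity of 32, stood at 1.41 ± 0.14. Nr4a1 stood at 1.00 ± 0.12 but Egr1 at -0.72 ± 0.08. For NF-kB feedback genes, 2 lay above it, 3 lay below it and 12 did not pass (3 and 5 adjusted over the list alone; adjusted p = 0.214). For cholesterol biosynthesis, none lay above it, none lay below it and 16 did not pass (0 and 2 adjusted over the list alone; adjusted p = 6.25e-05, but adjusted p = 0.326 with an estimated correlation), with a median of -0.16.

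**Figure D2:**
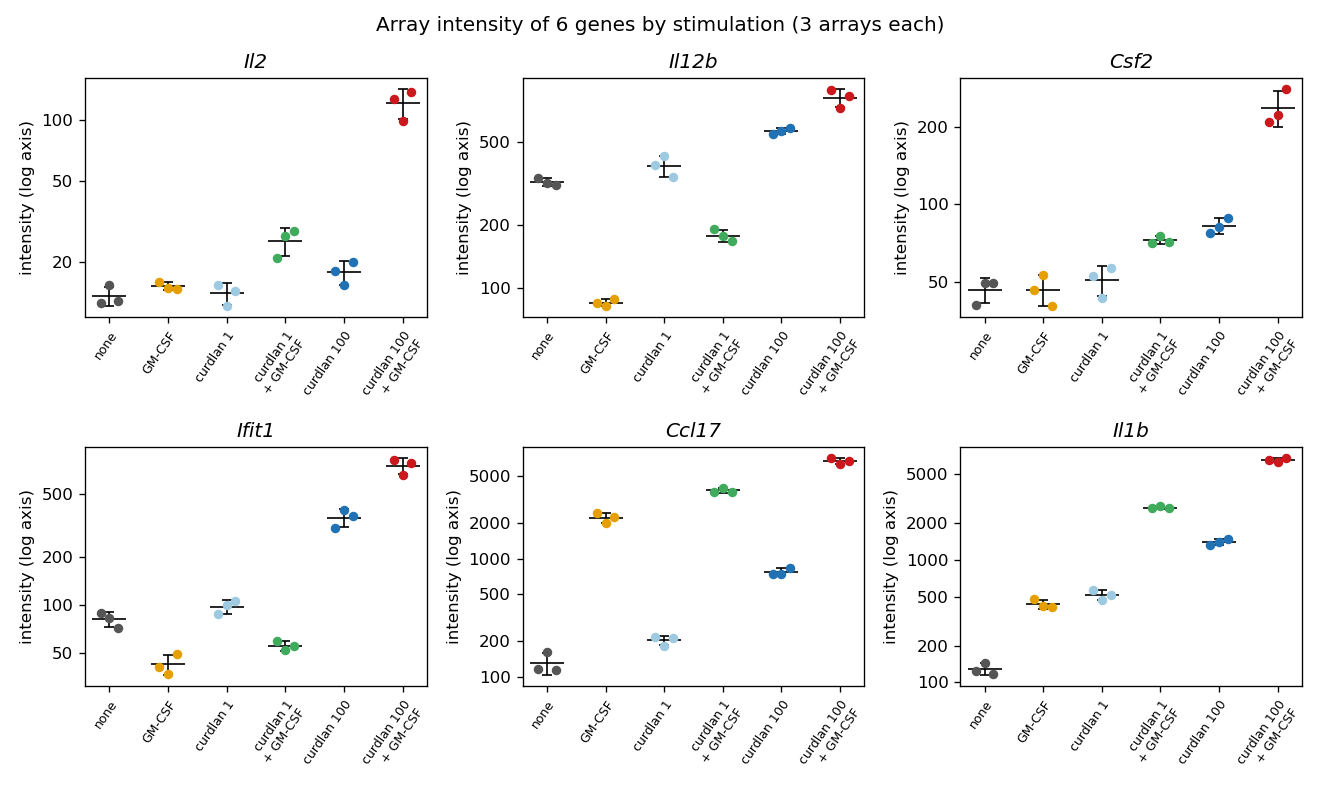
Points are the intensities of single arrays on a log axis for 6 genes and the 6 groups, with lines for the mean ± SD of 3 arrays. Il2 reached 121 with curdlan 100 and GM-CSF together and had group means of at most 25.3 elsewhere, Il12b fell from 322 to 85.5 with GM-CSF alone and reached 807 in the combination, and Ccl17 reached 6725.

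At the low dose the interaction held 8 genes. Il1a lay above the product by 1.32 ± 0.11 (adjusted p = 3.09e-05) and Ptgs2 by 1.18 ± 0.14 (adjusted p = 0.00185), and both passed in each alternative that was run. The Ptgs2 means unstimulated and with GM-CSF lay close to the filter's intensity of 32, where the effect of GM-CSF alone may be understated. The other 6 each lost the call in at least 1 alternative. Cxcl3 (1.33 ± 0.21, or 1.72 with intensities under 32 set to 32), Il12b (0.81 ± 0.11), Igsf6 (0.50 ± 0.09) and Dcun1d3 (0.46 ± 0.08) lay above the product, and Gem, a small GTPase gene (-0.79 ± 0.13), and Egr1 (-0.65 ± 0.08) below it. Il12b and Egr1 lost it against the sum of the single increments and with a minimum change of 2-fold. Of the 8 genes, 4 were called above the sum as well and none below it, so Gem lost the call there too. As a list, cytokine genes lay higher (median 0.21): 2 lay above it, none lay below it and 21 did not pass (7 and 0 adjusted over the list alone; adjusted p = 1.49e-09). An estimated correlation gave an adjusted p of 0.00299. None of the 23 interferon response genes passed on either adjustment (median 0.03; adjusted p = 0.72). The 17 NF-kB feedback genes counted none above, none below and 17 not passing (7 and 1 adjusted over the list alone; adjusted p = 5.4e-06, but adjusted p = 0.387 with an estimated correlation). The count was 4 without curdlan 1 replicate 2, GM-CSF replicate 3, unstimulated replicate 1 or the first array of curdlan 1 with GM-CSF. It was 5 without GM-CSF replicate 2 or the third array of curdlan 1 with GM-CSF, 13 without curdlan 1 replicate 1 or unstimulated replicate 2, and 15 without GM-CSF replicate 1. Other processing gave 3 to 42 genes.

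The effect of GM-CSF itself differed between the curdlan doses for 200 genes, 104 with a higher and 96 with a lower change at curdlan 100 than at curdlan 1, 17 of them by at least 2-fold. Mx1 differed by 2.12 ± 0.14, and Rsad2 by 1.95 ± 0.18, and in the other direction Ccl12 by -1.38 ± 0.23 and Ccl17 by -1.12 ± 0.16. The largest adjusted p was 0.00543. Il2, with 3 of its 4 groups under 32, differed by 1.91 with intensities under 32 set to 32. Of 23 interferon response genes 14 were higher, none were lower and 9 did not pass (18 and 0 adjusted over the list alone) at the high dose, and an estimated correlation gave an adjusted p of 0.00769. For cytokine genes, 6 were higher, none were lower and 17 did not pass (9 and 0 adjusted over the list alone; adjusted p = 5.15e-08), with Csf2 at 0.99 ± 0.17. NF-kB feedback genes leaned the other way, and none were higher, 4 were lower and 13 did not pass (0 and 10 adjusted over the list alone; adjusted p = 8.56e-08, but adjusted p = 0.141 with an estimated correlation). Icam1, an adhesion molecule gene, stood at -0.55 ± 0.07. The count was 119 without the third array of curdlan 1 with GM-CSF, 129 without the third array of curdlan 100 with GM-CSF, and 488 with array weights. More of the changes were lower than higher with array weights (271 and 217), trended, robust variances (164 and 132), a log2 value of at least 7 (158 and 125) and the mean over probe sets (118 and 92). They were so too without curdlan 1 replicate 1 (88 and 74), curdlan 100 replicate 3 (139 and 124) or the first array of curdlan 100 with GM-CSF (96 and 89).

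Measured against the sum of the single increments on the linear scale instead of their product, the combination of curdlan 100 and GM-CSF had 231 genes above and 178 below of 13077 that could be tested. On both scales 149 genes lay above and 126 below, and 7 of the 189 genes below the product lay above the sum. On the log2 scale Il12b lay above the sum by 1.30 ± 0.13, Il1b by 1.93 ± 0.08 and Ptgs2 by 1.59 ± 0.10. Csf2 lay above it by 1.52 ± 0.14 and Tnf by 0.71 ± 0.06, and the largest adjusted p of these was 1.29e-05. With intensities under 32 set to 32, Il2 lay 1.91 and Il6 1.90 above the sum. For Il2 each group behind the sum had a mean under 32, and for Il6 those unstimulated and with GM-CSF did. These sums were therefore not fully measured, and the distances depend on that setting. Among the 7 below the product and above the sum, Ccl17 lay 1.23 above the sum (adjusted p = 2.87e-06) and Ccl4 0.33 above it (adjusted p = 0.00361). Ccl12 (0.05), Gem (0.02), Egr1 (0.18), Cdc42ep2 (0.07) and Nlrp3 (0.13) were below the product and gave positive values against the sum that did not pass. At curdlan 1, 39 genes lay above the sum and 3 below.

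Marker genes of dendritic cell subsets and of other cells also moved. With GM-CSF alone, of 11 markers of conventional type 2 dendritic cells 6 rose, 4 fell and 1 did not pass (6 and 4 adjusted over the list alone; adjusted p = 0.133). They include the lectin genes Mgl2 (1.76 ± 0.10), Clec10a (1.12 ± 0.08) and Cd209a (1.07 ± 0.07) and the transcription factor gene Irf4 (1.24 ± 0.06). Type 1 markers gave 5 higher, 2 lower and 3 not passing (5 and 2 adjusted over the list alone; adjusted p = 0.0292, but adjusted p = 0.382 with an estimated correlation), with Naaa at 1.13 ± 0.06 and Batf3 at 0.84 ± 0.06. Camera gave them 0.0684 with the mean over probe sets, 0.061 with quantile normalization and 0.069 without unstimulated replicate 1, the highest over left-out arrays. Plasmacytoid markers gave 2 higher, 1 lower and 9 not passing (2 and 1 adjusted over the list alone; adjusted p = 0.306). Monocyte and macrophage markers gave 2 higher, 7 lower and 5 not passing (2 and 8 adjusted over the list alone; adjusted p = 0.415), and neutrophil markers 2 higher, 3 lower and 6 not passing (2 and 3 adjusted over the list alone; adjusted p = 0.952). With curdlan 100, type 2 markers gave 2 higher, 3 lower and 6 not passing (2 and 4 adjusted over the list alone; adjusted p = 0.907), with Klf4 at -0.92 ± 0.07 and Cx3cr1 at 0.82 ± 0.07. Type 1 markers gave 1 higher, 3 lower and 6 not passing (1 and 3 adjusted over the list alone; adjusted p = 0.629). Monocyte and macrophage markers gave 1 higher, 4 lower and 9 not passing (1 and 4 adjusted over the list alone; adjusted p = 0.25), with Cd14 at 0.80 ± 0.05 and Mertk at -0.63 ± 0.07. Plasmacytoid markers gave 3 higher, 1 lower and 8 not passing (3 and 1 adjusted over the list alone; adjusted p = 0.247), with Ly6d at 0.69 ± 0.07. With curdlan 1 the plasmacytoid list lay higher (median 0.13; adjusted p = 3.86e-05, but adjusted p = 0.0764 with an estimated correlation). So did the neutrophil list, none of whose members passed (median 0.15; adjusted p = 0.00216, but adjusted p = 0.302 with an estimated correlation), and camera gave it 0.0696, the highest over left-out arrays, without unstimulated replicate 1.

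In lists of more distant cell types 1 or 2 genes each passed with GM-CSF alone. Of 9 mast cell and basophil markers 1 rose, 1 fell and 7 did not pass (0 and 0 adjusted over the list alone; adjusted p = 0.678). Of 4 eosinophil markers 1 rose, 1 fell and 2 did not pass (1 and 1 adjusted over the list alone; adjusted p = 0.952). T, B and NK cell markers gave none higher, 1 lower and 11 not passing (0 and 1 adjusted over the list alone), Cd4 at -0.30 ± 0.06 (adjusted p = 0.952). Among 3 erythroid markers 1 rose, 1 fell and 1 did not pass (1 and 1 adjusted over the list alone; adjusted p = 0.678). The member that rose was Car2, a carbonic anhydrase gene (2.24 ± 0.09), so that the median (-0.14) and mean (0.64) differed in sign. Of 11 housekeeping controls 1 rose, 3 fell and 7 did not pass (1 and 3 adjusted over the list alone), the largest change that of Gusb (-0.31 ± 0.05; list adjusted p = 0.678).

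Genes of the receptors for both agents moved little. Clec7a, which encodes Dectin-1, rose by 0.37 ± 0.04 with GM-CSF alone (adjusted p = 3.55e-06). It rose by 0.51 ± 0.04 with GM-CSF over curdlan 100 (adjusted p = 1.5e-07) and changed by -0.18 ± 0.04 with curdlan 100 alone (adjusted p = 0.00492). Csf2rb, the shared β chain of the GM-CSF receptor, rose by 0.20 ± 0.04 with GM-CSF (adjusted p = 0.000411), and Csf2ra, the α chain, gave -0.12 ± 0.07, which did not pass (adjusted p = 0.23). Of 18 genes for GM-CSF and haematopoietic cytokine receptors 6 rose, 8 fell and 4 did not pass (6 and 9 adjusted over the list alone; adjusted p = 0.952) with GM-CSF, with Il4ra at 0.88 ± 0.07 and Csf3r at -0.69 ± 0.07. Ccl22, a second CCR4 ligand gene, rose by 1.00 ± 0.06 with GM-CSF and by 1.28 ± 0.06 with curdlan 100 (adjusted p = 1.27e-09 and 5.72e-11). Its interaction of -0.13 ± 0.08 did not pass (adjusted p = 0.54). Il10 (intensities of 15.2 to 29.2) and Il23a (7.45 to 23.0) stayed below the filter in these arrays and were not tested.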

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

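Tests chosen only after a result was seen were those of plasmacytoid markers, of the sum of single increments as the cause of values below the product, of saturation in genes ranked by their expected level, and of reshuffled array deviations for the interactions and the dose difference. The test of Ifnb1 was set earlier, but its reading was changed after its levels were seen, as stated beside it.

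Effects differed between groups in 3 tests of the difference itself: 8 genes passed the interaction at curdlan 1, 389 that at curdlan 100, and 200 the difference of GM-CSF effects between the doses. Of 100 drawn splits of the arrays, 6, 7 and 8 gave as many genes, with highest other counts of 3840, 3617 and 3373, so these splits do not exclude chance. Splits that mix treated groups carry the single effects of GM-CSF and curdlan, and counts several times the real one point to that structure of the samples. When the arrays' deviations were instead reshuffled over group means without interaction, 1 of 100 drawings, the real data, gave as many genes in each case, and the highest of the others were 2, 6 and 6. The pairwise comparisons have 10 splits each, too few for a share under 0.05; in each 1 split, the real one, gave as many genes, with these values and highest others: GM-CSF 5259 and 0; curdlan 1 403 and 0; curdlan 100 3701 and 1; curdlan 100 against curdlan 1 2393 and 1. For GM-CSF added to curdlan 1 they were 5039 and 0 and to curdlan 100 5020 and 0, for curdlan 1 and 100 added to GM-CSF 489 and 0 and 4132 and 1, and for the doses with GM-CSF 2961 and 0.

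Cytokine genes had a median interaction at curdlan 100 of 0.451, and the list test called this difference between the effects of GM-CSF with and without curdlan. Probe sets annotated to several genes or to none, which no comparison of the report uses, also changed: of 4659, limma called 774 with GM-CSF, 574 with curdlan 100 and 37 in the interaction at curdlan 100.

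Interferon response genes had a median interaction of 0.722 at curdlan 100, called as a difference between groups. For members that GM-CSF alone lowered and curdlan 100 raised, the distance above the product is larger than that above the sum by arithmetic. The list was not tested against the sum. Dim signals are argued against by the 18 members with every group mean at 64 or more, whose median was 0.668 with 12 called above and none below, and a single array by the lowest median of 0.648 when each of 12 arrays was left out. A gain of plasmacytoid cells, which secrete interferon, would have to come from cells left by the sort for CD11b, which they carry at low levels; the median interaction of their markers was -0.0681 over members that went both ways, 1 of 12 was called above, and with GM-CSF over curdlan 100 the median was 0.000646, values that do not decide it. More interferon beta transcript may contribute and cannot be told apart from none: Ifnb1 had an interaction of 0.107 (adjusted p = 0.865), which met the bound set against it, but its group means of 27.6 to 37.0 lie near the low end of the array, where a change would be hidden. The highest of these means was that of curdlan 100 with GM-CSF. In limma that group differed by 0.36 ± 0.13 from curdlan 1 with GM-CSF (adjusted p = 0.0554). From curdlan 100 alone it differed by 0.19 ± 0.13 (adjusted p = 0.255), and neither difference passed. A biological effect of the combination itself remains among the open explanations, and interferon protein was not measured here.

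GM-CSF and curdlan 100 each gave more decreases than increases, 36.7% and 36.8% of the passing genes being higher, although changes of at least 2-fold were 65.9% and 91.0% higher and smaller ones 35.7% and 34.6%. A shift in scale of whole arrays that remains in the deposited values is argued against as the whole cause. Centring each array left the larger of both shares at 35.0%. A remaining difference in the shape of the value distribution is argued against as the whole cause too. Quantile normalization raised the shares to 41.2% for GM-CSF and 40.5% for curdlan 100, so such a difference may account for part of the excess of decreases. The deposited values were already summarised with RMA and had array medians of 49.8 to 51.2, so centring had little left to change. Neither test can show what the original processing did to these shares. What stays open, beside that processing, is a broad change in RNA content, which intensities normalized to a common level could not show, and a biological decrease of many transcripts.

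Genes that both agents raised at least 2-fold mostly lay below the product in the combination: of 28, with a median interaction of -0.50, 18 were called below and 2 above. The dimmest part does not decide on array saturation. By combined level it had a median of -0.339, which met the bound set against saturation, but that ranking uses a level which the interaction itself sets. Ranked by the level expected from the product, the lowest part had -0.191, short of the bound, and the brightest -0.625. The middle part had -0.625 as well, with expected levels of 1610 to 4070 on arrays that reach 17270 or more. Those levels lie well below the arrays' highest intensities, but where single probe sets level off was not measured, so saturation stays undecided there. The brightest part had expected levels of 4080 to 21700, the highest of them above any intensity on these arrays, so saturation may contribute in that part. Whether these genes fall short depends on the scale: of the 18 called below the product, 88.9% (16) lay at or above the sum of the single increments, 7 of them called above it and none below. For genes that both agents raise, the sum is smaller than the product by arithmetic, so this share does not identify a cause. A ceiling of induction in the cells is a biological alternative that was not tested, and both single effects share the unstimulated arrays, which biases this selection toward values below the product.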

How the results depend on the processing

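The alternative with intensities under 32 set to 32 was chosen after the results were seen, the others before, and each ran. It moved the interaction at curdlan 1 to 20 genes and no other count by over 1.5 times; the cause was not tested. A minimum change of 2-fold left, by its construction, 170 genes for GM-CSF, 17 for curdlan 1, 144 for curdlan 100, 54 between the doses, 160 and 132 for GM-CSF added to curdlan 1 and 100, 29 and 172 for curdlan 1 and 100 added to GM-CSF, 67 between the doses with GM-CSF, 3 and 28 for the interactions at curdlan 1 and 100, and 17 for the difference of GM-CSF effects. With array weights the counts for curdlan 1 with GM-CSF against GM-CSF, the difference of GM-CSF effects and the interaction at curdlan 1 were 850, 488 and 29; the cause was not tested. With trended, robust variances curdlan 1 gave 666 genes and its interaction 40; the cause was not tested. The compared groups alone, with fewer samples behind the spread, gave 166 for curdlan 1, 1257 between the doses and 5 for the interaction at curdlan 1, which further gave 35 with a log2 value of at least 7, 16 with the mean over probe sets, 5 without a filter, 5 with the replicate block and 42 against the sum; the cause was not tested. The block moved no other count by over 1.5 times, and the numbers do not pair the arrays over all groups: of 45 same-number pairs across groups 16 had residual r over 0.1 (range -0.451 to 0.433, median -0.0144, across genes, which are not independent replicates), and 7 of 18 arrays correlated best with their own number. The 3 pairs of GM-CSF and curdlan 1 had 0.433, 0.340 and 0.280, so a pairing of these groups stays open. Leaving out single arrays gave 4569 to 4874 genes for GM-CSF, 215 to 362 for curdlan 1, 2957 to 3520.0 for curdlan 100, 1812 to 2243 between the doses, 4333 to 4744 and 4119 to 5057 for GM-CSF added to curdlan 1 and 100, 352 to 406 and 3221 to 3734 for curdlan 1 and 100 added to GM-CSF, 1998 to 2539 between the doses with GM-CSF, 4 to 15 and 295 to 392 for the interactions, and 119 to 263 for the difference of effects. The lowest counts of curdlan 1 and of the difference were those without unstimulated replicate 1 and without the third array of curdlan 1 with GM-CSF; without the third array of curdlan 100 with GM-CSF the difference held 129. Against the sum the interactions at curdlan 100 of Ccl12 (0.0537), Ccl17 (1.23), Ccl4 (0.33), Cdc42ep2 (0.0668), Egr1 (0.18), Gem (0.02) and Nlrp3 (0.13) turned positive, since a sum is smaller than a product of increases. With the mean over probe sets Polr2a in curdlan 100 with GM-CSF against curdlan 100 (0.0054) and Tlr7 in curdlan 100 (0.0368) turned; the cause was not tested. List medians near 0 turned for glycolysis in curdlan 100 with centred arrays (-0.0042), inflammasome in curdlan 1 with array weights (0.0182) or without unstimulated replicate 1 (0.0015; -0.048, with the call lost, without curdlan 1 replicate 1), and inflammasome in curdlan 1 with GM-CSF against GM-CSF with a log2 value of at least 7 (-0.0001) or without GM-CSF replicate 2 (-0.0178; 0.0502 without GM-CSF replicate 3); the cause was not tested. Over named genes and alternatives 17952 values kept direction and side of the threshold, 97 gained a call, 827 lost one and 9 turned, and over lists 5297, 109, 133 and 5; an estimated correlation accounted for 68 of the lost list calls. No scaling moved the median of all genes by over 0.0206, and signals near the low end limit what can be seen for Il2, Ifnb1, Il10 and Il23a.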

Other observations

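F3, Edn1, Inhba and Serpinb2 were picked after their values were seen, and as a set they were not tested. F3, which encodes the clotting initiator tissue factor, rose by 3.09 ± 0.12 when GM-CSF was added to curdlan 100 (adjusted p = 1.8e-11). Edn1, the vasoconstrictor endothelin-1, rose by 2.78 ± 0.16 between the curdlan doses in the presence of GM-CSF, with an interaction at curdlan 100 of 1.92 ± 0.22 (adjusted p = 0.000137). Inhba gave an interaction of 1.86 ± 0.13 (adjusted p = 8.7e-07) and Serpinb2, an inhibitor of plasminogen activators, one of 1.18 ± 0.17 (adjusted p = 0.00101).

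Members of the prostanoid and leukotriene list went both ways. Ptgs2, which makes prostaglandin precursors, had levels of 36.3 ± 1.14 unstimulated, 41.8 ± 3.74 with GM-CSF, 339.5 ± 17.0 with curdlan 100 and 1045 ± 154 with both. Hpgd, which inactivates prostaglandins, had levels of 262 ± 11.3, 69.6 ± 4.01, 95.2 ± 9.20 and 39.5 ± 2.55 in the same order, the last close to the filter's intensity of 32. The receptor gene Ptger2 changed by -1.24 ± 0.06 with GM-CSF, -1.27 ± 0.06 with curdlan 100 and -0.90 ± 0.06 with curdlan 100 over GM-CSF. As a whole the list of 16 genes counted 5 higher, 8 lower and 3 not passing (5 and 8 adjusted over the list alone; adjusted p = 0.455) with curdlan 100 over GM-CSF, its median of -0.14 and mean of 0.15 differing in sign.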
